A study of Mus musculus with 10 samples.

How the data were processed

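Single myofibres were isolated from the extensor digitorum longus of C57BL/6 mice with collagenase (400 U per ml, 2 hours), per the labels' protocols, and grouped by age and by p21 RT-PCR. Libraries were made from 1 ng of RNA with the SMART-Seq v4 kit, which amplifies full-length cDNA, and from 150 pg of cDNA with Nextera XT and 12 PCR cycles, per the same protocols. Reads were aligned with TopHat2 2.1.1 to mm10, per the submitters' processing notes. The deposited table held counts of reads per gene, whole numbers made by the authors with no normalisation, with the position of each gene. The counting tool, the annotation, the use of strand and the number of mice are not given in the sources used here, and the kit does not mark strand. The labels give no batch. The table had 24576 gene entries, of which 140 shared 67 repeated names, 16901 had at least 1 read, 0 named no gene and 0 were mitochondrially encoded.

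The total counts per column were 20652306, 22158751 and 22579097 for Young-p21-Low replicates 1 to 3, 17767605, 18171802 and 21478179 for Old-p21-Low replicates 1 to 3, and 20010830, 22349781, 19685440 and 22564387 for Old-p21-High replicates 1 to 4. The 20 genes with the highest counts held 18.2 to 39.0% of the reads of a sample. The number of reads sets the precision of low counts only, since amplified reads without molecular identifiers are not independent molecules.

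Columns were first compared in pairs by a chi-square per gene with at least 20 reads. Old-p21-High replicates 1 and 4 were then replaced by their rounded mean, with 21287455 reads, so that 9 samples were tested. The design fixed before the data were examined had all 10 columns as separate libraries, and the fit of 10 columns was kept as an alternative.

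Groups, tests, gene lists and the rule for named genes were chosen at the same time. Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F-test after TMM scaling and filterByExpr by group, in a one-way model of the 3 groups with 6 residual degrees of freedom. Of the genes, 11303 were tested, with Benjamini-Hochberg adjustment in each comparison and a threshold of 0.05. The common biological coefficient of variation was 0.452. TMM factors were 1.16, 1.36 and 1.07 in Old-p21-High and 0.83 to 1.01 in the other samples. Values per sample are CPM on TMM-scaled library sizes, and standard errors were computed as the size of the log2 fold change over the square root of F. Named p values are edgeR adjusted p unless a sentence names another test. Cdkn1a and the Myh4 share were also compared by exact two-sided permutation tests (in R, 20 regroupings), adjusted over 6 tests. Floors are 3 counts and confidence intervals 95%, by the exact Clopper-Pearson method.

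The 36 gene lists held 872 genes, of which 857 were in the table. They covered p53 targets, kinase inhibitors, BCL2 family, secreted factors, NF-kB, interferon, stress responses, protein turnover, the neuromuscular junction, the sarcomere, calcium handling, energy metabolism, ribosomal proteins, the circadian clock, proliferation and 9 other cell types. The fast and slow sarcomere lists also held genes of those fibre types outside the sarcomere, such as Ampd1 in the fast list and Fabp3 in the slow and oxidative list. The 31 lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with the correlation estimated from the data. The second form was weaker even for a list whose estimated correlation was below the preset one. A call lost in it therefore does not show that members vary together.

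By the rule for named genes, each comparison gave Cdkn1a, then the 8 largest rises and 8 largest falls among genes with an adjusted p below 0.05, CPM ranges that did not overlap and a mean of at least 10 CPM in the higher group. To these came up to 3 passing members, by smallest p, of each list that was called or had at least 3 passing members. Where fewer than 5 genes passed these conditions, the 5 smallest p in each direction were given as values. Predicted genes were counted and not named, and Cdkn2a and 4 myosin heavy chain genes were always reported. The rule took 81, 14 and 80 genes, of which the text names a part, chosen after their values were seen: the largest changes, and list members from called lists or with stable calls. Pfkfb3 and Itm2a fell outside the rule, as did Ccdc141 and Smoc2 in the comparisons where it did not take them, and were also chosen after their values were seen. Gene positions were those of the table. Of its entries 6454 overlap another entry, and overlapping named genes are pointed out because their reads cannot be assigned without strand.

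The test was checked on simulated counts for 11303 genes, 5 draws per comparison with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 48.6% of 4-fold and 2.6% of 2-fold changes between Old-p21-High and Old-p21-Low, and 46.6% and 4.2% between Old-p21-High and Young-p21-Low. False calls were 9.86%, 8.68% and 12.4% of all calls in the comparisons of Old-p21-High with Old-p21-Low, Old-p21-Low with Young-p21-Low and Old-p21-High with Young-p21-Low, above the nominal level, and 5.24%, 6.32% and 6.56% with edgeR's legacy estimates. In 1 simulated set per comparison, a list moved 1.5-fold was called and 0 of 30 other lists were. Genes were drawn independently of each other, so these sets could not show false list calls where members vary together.

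The alternative settings chosen before the data were examined were RLE and upper-quartile scaling, leaving out the 20 genes of highest count, no filter, a filter of at least 10 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom with quality weights, edgeR's legacy estimates, robust spread, only the 2 groups compared, the replicate number as a block, leaving out each sample, and the number of detected genes as a covariate. The 10 columns as deposited, either column of the combined sample alone, and offsets for GC content and transcript length were added after seeing the data. Overlaps of calls and correlations of fold changes between comparisons were set beside 50 simulated data sets of unchanged groups. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the comparison of columns, tables and figures.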

Results

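RNA was sequenced from single myofibres of the extensor digitorum longus, a fast hindlimb muscle, of C57BL/6 mice aged 6 or 24 months. The fibres had been sorted into 3 groups by RT-PCR for p21, the cell cycle inhibitor encoded by Cdkn1a. Young-p21-Low fibres (3 columns of counts) came from the younger mice, and Old-p21-Low (3 columns) and Old-p21-High fibres (4 columns) from the older mice. Each column held 17767605 to 22579097 counted reads, and 11906 to 14049 genes had at least 1 read. The columns of Old-p21-High replicates 1 and 4 had a median chi-square per gene of 0.838 over 11176 genes, against 7.77 to 67.7 in the other 44 pairs of columns. The median ratio of replicate 1 to replicate 4 was 0.927 for genes that start below 90.7 Mb on their chromosome (mm10) and 0.816 for those above it. With 1 ratio on each side of this step the median chi-square was 0.126, where independent draws of reads would give 0.455, so the median gene differed by less than the sampling noise. As exceptions, 124 gene entries with at least 20 reads in replicate 1 had at most 0.1 times as many in replicate 4, and 13 entries the other way. The 2 columns were counted as 1 sample, by their mean, called the combined sample here, which left 3 samples in each group. Which fibres shared a mouse is not given in the sources used here, so the p-values measure only the spread between these samples, which may be partly technical. On the first principal component, with 36.3% of the variance, the Old-p21-High samples lay at 64.1 to 94.3 and the other 6 between -52.9 and -17.3.

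**Figure D1:**
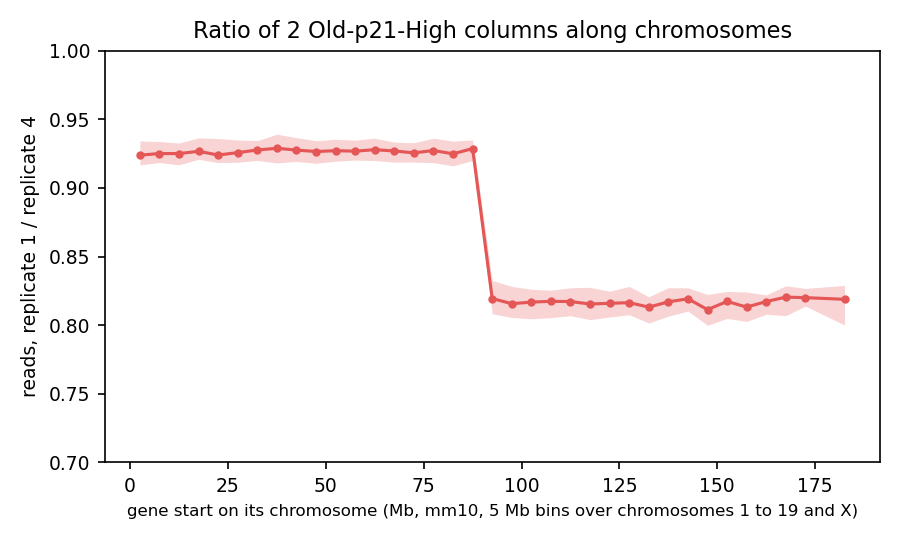
Ratio of the reads of Old-p21-High replicate 1 to those of replicate 4 (vertical axis, from 0.70) against the position of the gene start in Mb on its chromosome, over all chromosomes in bins of 5 Mb; points are medians over genes and the band spans the quartiles. The median ratio is 0.927 below 90.7 Mb and 0.816 above it.

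Cdkn1a (chromosome 17, 29090979 to 29100722, mm10) was measured first, as a check of the labels. It reached 395 ± 51.5 CPM in Old-p21-High (SD, n = 3), 49.9 ± 1.19 CPM in Old-p21-Low (SD, n = 3) and 61.0 ± 28.6 CPM in Young-p21-Low fibres (SD, n = 3). The log2 fold change of Old-p21-High over Old-p21-Low was 2.99 (SE 0.31, edgeR adjusted p = 4.4e-04), and over Young-p21-Low it was 2.70 (SE 0.30, edgeR adjusted p = 9.2e-04). Old-p21-Low differed from Young-p21-Low by -0.29 (SE 0.29, edgeR adjusted p = 0.760), not past the threshold, and by 0.14 without Young-p21-Low replicate 2. Exact two-sided permutation tests of log2 CPM gave p = 0.1, p = 0.7 and p = 0.1 for Old-p21-High against Old-p21-Low, Old-p21-Low against Young-p21-Low and Old-p21-High against Young-p21-Low. The smallest exact p for 3 samples against 3 is 0.1, and after adjustment over 6 permutation tests the values were 0.15, 0.7 and 0.15. Because the fibres were sorted by this transcript, its level is not an independent finding. Cdkn2a, the locus of the cell cycle inhibitor p16, had 0 reads in all 9 samples, which allows up to 0.0986 to 0.186 CPM per sample (3 counts), so a lower level was not detectable at this depth.

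**Figure D2:**
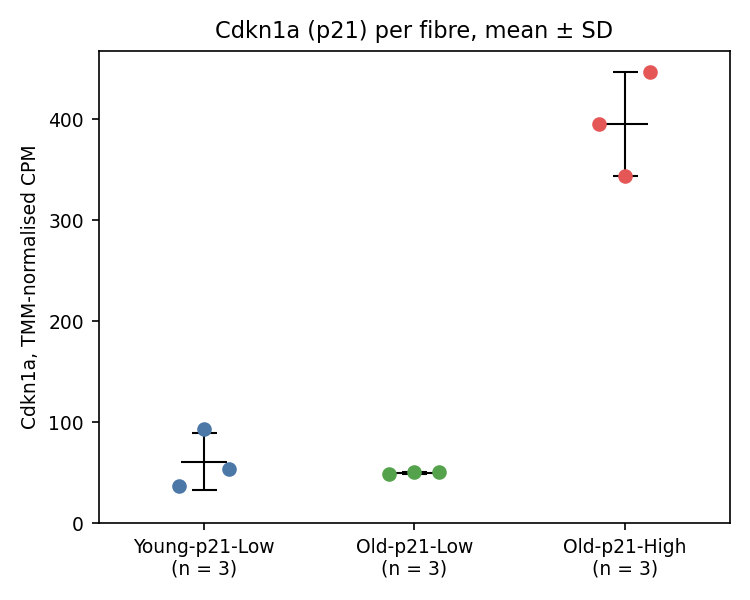
Cdkn1a in each sample, in CPM scaled by TMM, for the 3 groups; points are samples (replicates 1 and 4 of Old-p21-High are 1 point) and bars show the mean ± SD of 3 samples. The Old-p21-High samples lie between 344 and 447 CPM and the other 6 samples between 37.1 and 92.7 CPM.

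The comparison of Old-p21-High with Old-p21-Low fibres asked which transcripts differ with p21 level at the same age. Most genes of mitochondrial energy metabolism and of glycolysis were lower in Old-p21-High fibres. Of 59 nuclear-encoded oxidative phosphorylation subunits tested, 57 fell (59 adjusted over the list alone), with a median log2 fold change of -1.44. Among 23 tricarboxylic acid cycle genes 21 fell (22 adjusted over the list alone, median -1.33), and among 30 genes of fatty acid uptake and oxidation 23 fell (24 adjusted over the list alone, median -1.12). Of 29 glycolysis and glycogen genes 19 fell and 1, Pfkfb3, rose (21 and 1 adjusted over the list alone, median -1.44). Sdhd, a subunit of succinate dehydrogenase, was at 227 ± 13.6 against 982 ± 24.5 CPM (SD, n = 3 each; log2 fold change -2.11, SE 0.19). The complex I subunit Ndufb10 was at 125 ± 11.3 against 499.6 ± 16.5 CPM and Cycs, cytochrome c, at 17.6 ± 3.52 against 81.9 ± 20.1 CPM. Idh3a, of the mitochondrial isocitrate dehydrogenase (chromosome 9, 54586511 to 54604662), was at 488 ± 56.2 against 2894 ± 499.8 CPM, Sdhb, another succinate dehydrogenase subunit, at 285 ± 58.6 against 1422 ± 372 CPM, and the aspartate aminotransferase Got1 at 143 ± 33.5 against 984 ± 438 CPM. Lpl, lipoprotein lipase, was at 1.46 ± 1.01 against 112 ± 58.7 CPM, Acadm, the medium-chain acyl-CoA dehydrogenase, at 83.1 ± 14.4 against 527 ± 66.6 CPM, and Acaa2, a thiolase of fatty acid oxidation, at 36.6 ± 17.0 against 305 ± 90.2 CPM. Tpi1, triosephosphate isomerase (chromosome 6, 124810592 to 124814296), was at 263 ± 128 against 4182 ± 259 CPM, Pfkfb1 at 10.9 ± 5.33 against 114 ± 16.2 CPM, and the glycogen synthase Gys1 at 215 ± 62.1 against 1109 ± 301 CPM.

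The 12 genes given with their CPM had edgeR adjusted p values of 2.1e-04 to 0.00117, and each call held without any 1 of the 9 samples. The camera test with a preset correlation gave the 4 lists adjusted p values of 5.1e-44, 1.1e-21, 6.0e-17 and 4.1e-15 in the order above. None of these calls held when the correlation was estimated from the data: adjusted p = 0.171 with an estimated correlation for oxidative phosphorylation, the tricarboxylic acid cycle and glycolysis, and adjusted p = 0.1002 with an estimated correlation for fatty acid genes. Genes of mitochondrial import, dynamics and quality control were lower as a list, with 4 of 32 falling (4 adjusted over the list alone, median -0.36, camera adjusted p = 0.00165; adjusted p = 0.1002 with an estimated correlation). Among them were the prohibitin Phb (-1.50, SE 0.18) and the mitofusins Mfn2 (-1.38, SE 0.27) and Mfn1 (-1.34, SE 0.28), which act in mitochondrial fusion. The estimated correlation of this list was -0.0041, below the preset 0.01. Its unadjusted camera p still went from 4.2e-04 with the preset to 0.00685 with the estimated correlation. Lost calls are thus no measure of how far members vary together. Old-p21-High samples had 12669 to 13746 genes with a read and Old-p21-Low samples 11906 to 12649, and markers of other cell types took 0.119 ± 0.0107% and 0.0786 ± 0.0110% of their reads (SD, n = 3 each). With the number of detected genes as a covariate the median over all members of the 4 lists was -1.01, against -1.38 without it. Got1, Tpi1 and Mfn1 overlap another annotated gene, and without strand information the reads of overlapping parts cannot be told apart.

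Proteasome and NF-kB feedback genes were higher in Old-p21-High than in Old-p21-Low fibres. Of 32 proteasome subunits 19 rose (23 adjusted over the list alone, median 0.90, camera adjusted p = 4.1e-10; adjusted p = 0.501 with an estimated correlation). They included Psma5 (94.0 ± 15.8 against 32.6 ± 6.43 CPM), Psma1 (589.6 ± 76.2 against 251 ± 42.7 CPM) and Psmd14 (439 ± 68.9 against 195 ± 34.6 CPM). Of 17 NF-kB feedback and inflammatory genes 10 rose and 0 fell (11 and 1 adjusted over the list alone, median 1.65, camera adjusted p = 3.2e-06; adjusted p = 0.1002 with an estimated correlation). Birc3, an inhibitor of apoptosis induced by NF-kB, was at 136 ± 55.4 against 10.1 ± 1.72 CPM (log2 fold change 3.75, SE 0.34), while Map3k14, the NF-kB-inducing kinase, changed by 2.08 (SE 0.37) and the kinase Ripk2 by 1.69 (SE 0.36). Of 27 heat shock and chaperone genes 8 rose (10 adjusted over the list alone, median 0.58, camera adjusted p = 0.00515; adjusted p = 0.177 with an estimated correlation), among them Hsph1 (1.41, SE 0.27), Hsp90aa1 (1.14, SE 0.24) and Hspa1b (4.80, SE 1.10). Of 17 fast-fibre sarcomere genes 4 fell (8 adjusted over the list alone, median -0.85, camera adjusted p = 0.00110; adjusted p = 0.501 with an estimated correlation), among them Myoz1 (-1.75, SE 0.44), Myh1 (-4.48, SE 1.19) and Mylk2 (-1.36, SE 0.37). None of these 4 list calls thus held with an estimated correlation. Over the alternatives the fast sarcomere median ranged from -1.54 to -0.61. The lowest value came without the 20 genes of highest count, where list members among those 20 were left out.

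Of the genes named from these 4 lists, Hspa1b, Myoz1, Myh1 and Mylk2 lost their edgeR calls without single samples. Hspa1b did so without Old-p21-Low replicate 1 or 3 (highest adjusted p = 0.0674) and was at 2.59 without Old-p21-High replicate 2. Myh1 was at -1.60 without Old-p21-Low replicate 1 (adjusted p = 0.134) and lost its call also without any 1 Old-p21-High sample. Myoz1 lost it without Old-p21-Low replicate 3 (-2.06 to -1.37 over all samples left out, highest adjusted p = 0.0769). Mylk2 lost it without Old-p21-Low replicate 1 or 3 or Old-p21-High replicate 2 or 3 (highest adjusted p = 0.103). Hspa1b is nearly identical in sequence to Hspa1a and Myh1 overlaps another annotated gene, so their counts are uncertain.

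**Figure D3:**
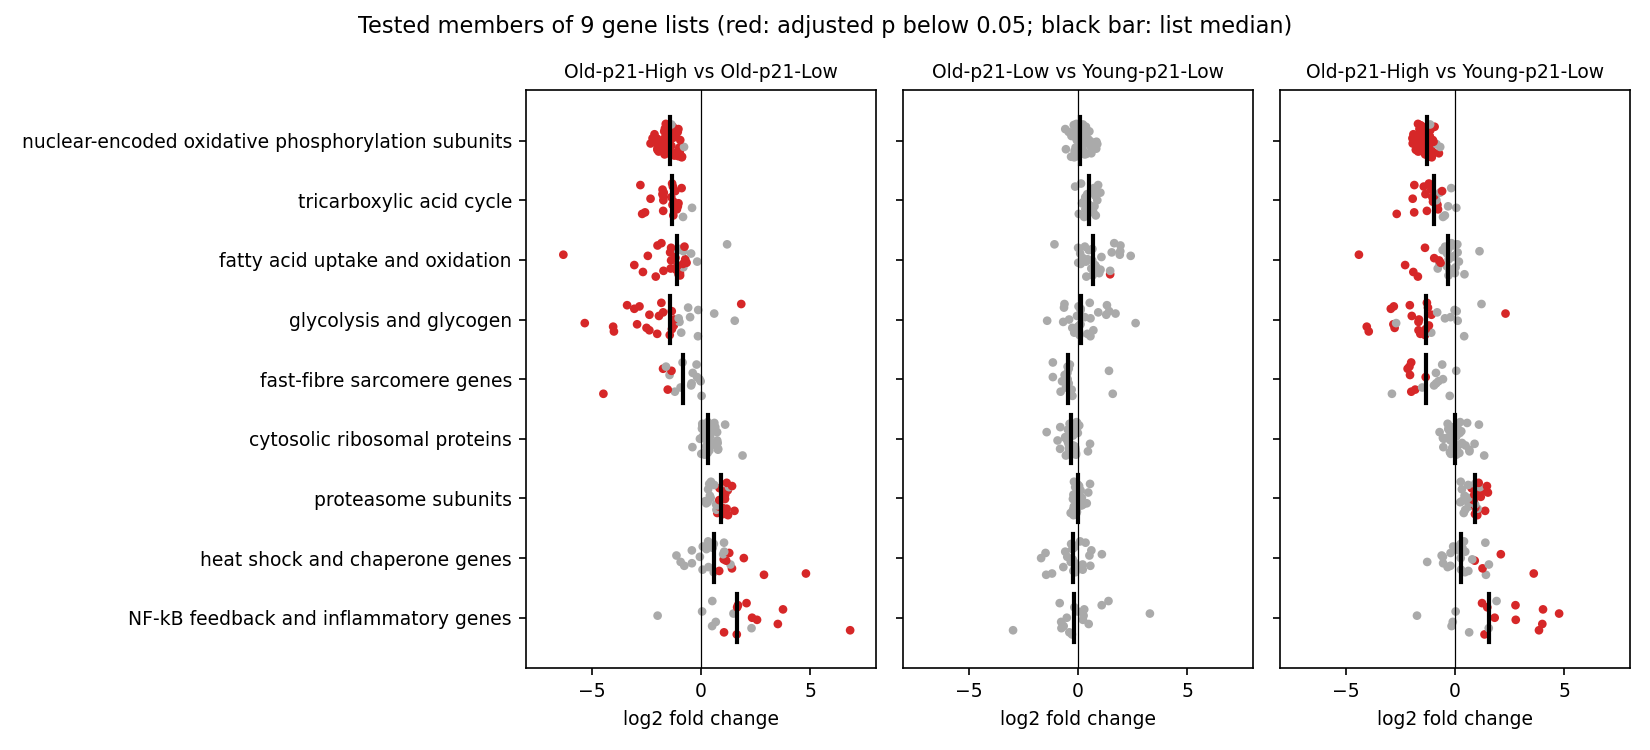
Log2 fold changes of the tested members of 9 gene lists (vertical axis) in the 3 comparisons (panels); each point is 1 gene, red points have an adjusted p below 0.05, and black bars mark list medians. The medians of the oxidative phosphorylation list are -1.44, 0.10 and -1.28 for Old-p21-High against Old-p21-Low, Old-p21-Low against Young-p21-Low and Old-p21-High against Young-p21-Low, and those of the proteasome list 0.90, -0.02 and 0.91.

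Over all genes, 1979 of 11303 tested differed between Old-p21-High and Old-p21-Low fibres (edgeR adjusted p below 0.05), 875 higher and 1104 lower, and 1574 of them changed at least 2-fold. At an unadjusted p below 0.05 there were 3720 genes, and the ranges of the 2 groups did not overlap in 35.7% of genes, against 10% by chance. The largest rises by the rule for named genes were Krt18, a keratin of simple epithelia (9.86, SE 2.21), Rassf4 (7.07, SE 1.11), Gdnf, a neurotrophic factor (6.35, SE 0.69), Tmem100 (5.44, SE 1.07), the collagen-crosslinking enzyme Lox (5.33, SE 1.58), Smoc2 (5.23, SE 0.94), the innate immune receptor Tlr2 (5.21, SE 1.48) and Plekho2 (4.99, SE 0.95). Smoc2, a secreted matricellular protein (chromosome 17, 14279506 to 14404790), was at 439 ± 97.3 against 11.6 ± 14.5 CPM, Tmem100 at 211 ± 116 against 4.79 ± 3.34 CPM and Gdnf (chromosome 15, 7810048 to 7837580) at 17.0 ± 7.58 against 0.210 ± 0.193 CPM. The largest falls were Perm1, a regulator of mitochondrial genes in muscle (-7.21, SE 0.51), Snai3 (-6.60, SE 0.72), Kbtbd13 (-6.39, SE 0.74), Lpl (-6.31, SE 0.69), Sh3kbp1 (-6.24, SE 0.81), Smco1 (-6.03, SE 0.26), Ptprs (-6.00, SE 0.76) and Emid1 (-5.73, SE 0.61). Perm1 (chromosome 4, 156215927 to 156221307) was at 2.20 ± 0.836 against 321 ± 149 CPM and Smco1 (chromosome 16, 32271609 to 32274779) at 2.73 ± 0.805 against 177 ± 19.2 CPM.

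All 8 falls, and the rises of Rassf4, Gdnf, Tmem100, Smoc2 and Plekho2, kept their edgeR calls without any 1 of the 9 samples, but several moved. Without Old-p21-Low replicate 2, Rassf4 was at 11.79, Smoc2 at 6.91 and Gdnf at 7.17. Plekho2 (3.61) and Emid1 (-5.03) moved most without Old-p21-High replicate 2, Snai3 (-7.59) without Old-p21-High replicate 3 and Kbtbd13 (-8.10) without the combined sample. Krt18 ranged from 2.11 to 876 CPM in the Old-p21-High samples, was at 4.93 without Old-p21-High replicate 2, and lost its call without Old-p21-Low replicate 1 or 3 (highest adjusted p = 0.0924). Lox lost its call without Young-p21-Low replicate 3, any 1 Old-p21-Low sample, Old-p21-High replicate 3 or the combined sample (3.43 to 12.59, highest adjusted p = 0.154). Tlr2 was at 1.75 without Old-p21-High replicate 2 (adjusted p = 0.248) and lost its call also without Young-p21-Low replicate 2 or Old-p21-Low replicate 1 or 3. Rassf4, Smoc2 and Ptprs overlap another annotated gene. The number of changed genes was 1290 without Old-p21-Low replicate 1, 1005 without Old-p21-Low replicate 3 and 91, all of them among the 1979, with the number of detected genes as a covariate. It was 1657 with edgeR's legacy estimates, whose share of false calls in the simulated counts was lower.

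**Figure D4:**
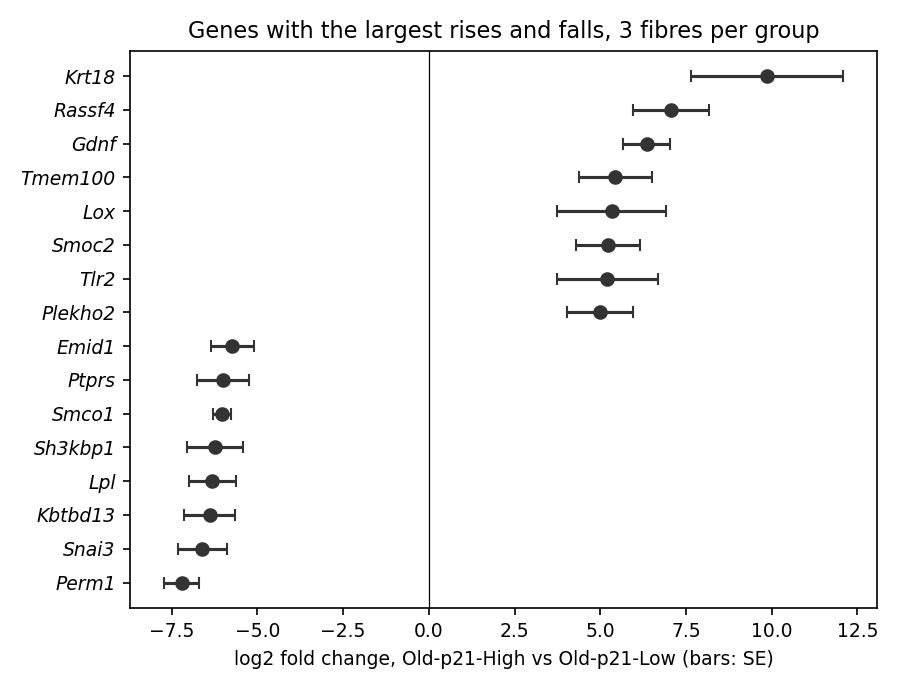
The 16 genes with the largest changes between Old-p21-High and Old-p21-Low fibres by the rule for named genes; points show the log2 fold change and bars its standard error. The values run from -7.21 for Perm1 to 9.86 for Krt18.

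Members of several other lists moved in both directions between Old-p21-High and Old-p21-Low fibres, and none of these lists was called (camera adjusted p from 0.161 to 0.953). Of 29 p53 target genes other than Cdkn1a, 5 rose and 3 fell (6 and 3 adjusted over the list alone). The rises included Eda2r, a receptor for ectodysplasin (chromosome X, 97333841 to 97377209), at 1602 ± 309 against 82.2 ± 34.1 CPM, Mdm2, the ubiquitin ligase of p53, at 364 ± 17.5 against 95.1 ± 7.38 CPM, and Gadd45a, a DNA damage response gene, at 739 ± 191 against 152 ± 73.3 CPM. Of 21 secreted factors associated with senescence 2 rose and 2 fell (2 and 2 adjusted over the list alone). The chemokine Cxcl10 changed by 4.77 (SE 0.81; 3.94 without the combined sample), Igfbp5 by 3.30 (SE 0.51) and the cytokine Il15 by -5.13 (SE 0.41). Of 23 atrophy, ubiquitin ligase and FoxO genes 5 rose and 1 fell (5 and 1 adjusted over the list alone). Trim63 (chromosome 4, 134315120 to 134329629) and Fbxo32, ubiquitin ligases of muscle atrophy, were at 3221 ± 466 against 819 ± 183 CPM and 1725 ± 339 against 548 ± 227 CPM, and Fbxo30 at 492 ± 55.6 against 139.7 ± 61.0 CPM. Of 26 denervation and neuromuscular junction genes 5 rose and 6 fell (6 and 6 adjusted over the list alone). Musk, the receptor kinase of the neuromuscular junction, changed by 3.34 (SE 0.31), the deacetylase Hdac4 by 2.57 (SE 0.24), and Ache, acetylcholinesterase, by -2.43 (SE 0.27). Gadd45a, Cxcl10 and Ache overlap another annotated gene.

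Of 28 NRF2 targets, antioxidants and metallothioneins 6 rose and 4 fell (6 and 5 adjusted over the list alone), with Nqo1 at 1.68, Sod2 at -1.26 and Prdx5 at -1.13 on the log2 scale. Of 37 autophagy and lysosome genes 5 rose and 3 fell (8 and 3 adjusted over the list alone), among them the proton pump subunits Atp6v1a (1.70) and Atp6v1h (1.44) and the protease Ctsb (-1.37), which overlaps Fdft1. Of 26 calcium handling genes 4 fell (4 adjusted over the list alone), including Hrc (-1.92, SE 0.26) and Sypl2 (-1.40, SE 0.31). Of 10 genes in the list of slow-fibre and oxidative-fibre genes 1 rose and 2 fell (1 and 4 adjusted over the list alone). The rise was Tpm3 (2.74, SE 0.58), which lost its call without Old-p21-Low replicate 3 (adjusted p = 0.0509). The falls were Fabp3 (-2.89, SE 0.29) and Smtnl1 (-2.82, SE 0.39). Of 23 stretch and myofibril repair genes 2 rose and 1 fell (2 and 1 adjusted over the list alone), with Anxa4 at 1.83 and Fhl1 at -4.21, or -2.58 without Old-p21-Low replicate 1. Interferon response genes rose in 2 and fell in 3 of 18 cases (2 and 3 adjusted over the list alone), unfolded protein response genes rose in 4 of 26 (4 adjusted over the list alone), immediate-early genes rose in 2 and fell in 2 of 27 (1 and 1 adjusted over the list alone) and circadian clock genes rose in 3 of 20 (3 adjusted over the list alone). None of 41 cytosolic ribosomal protein genes, 14 proliferation genes, 5 cyclin-dependent kinase inhibitors other than Cdkn1a or 4 anti-apoptotic BCL2 family genes passed the edgeR test, over all genes or adjusted over the list alone. The median, mean and camera direction differed in sign for p53 targets (median -0.13, mean 0.34, camera up), secreted factors (median -0.25, mean 0.03, camera down), immediate-early genes (median 0.19, mean -0.11, camera up), proliferation genes (median 0.05, mean 0.06, camera down) and satellite cell markers (median 0.29, mean -0.80, camera down).

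Myosin heavy chain transcripts were almost all Myh4, the fast IIB form, in every sample. The share of Myh4 among the reads of Myh4, Myh1, Myh2 and Myh7 was 99.6 ± 0.134% in Old-p21-High, 97.4 ± 2.96% in Old-p21-Low and 98.7 ± 1.11% in Young-p21-Low fibres (SD, n = 3 each). Exact two-sided permutation tests gave p = 0.1, p = 0.5 and p = 0.1 for Old-p21-High against Old-p21-Low, Old-p21-Low against Young-p21-Low and Old-p21-High against Young-p21-Low, where 0.1 is the smallest possible, and 0.15, 0.6 and 0.15 after adjustment over 6 tests. Old-p21-Low replicate 1 had a Myh4 share of 94.0% (exact 95% interval 93.9 to 94.1%) and a Myh1 share of 5.67% (5.60 to 5.73%). Without it the difference in Myh4 share went from 2.22 to 0.51 points between Old-p21-High and Old-p21-Low fibres and from -1.29 to 0.42 points between Old-p21-Low and Young-p21-Low fibres. In CPM, Myh4 was at 16583 ± 10465, 16365 ± 9132 and 19619 ± 4358 in Old-p21-High, Old-p21-Low and Young-p21-Low fibres, Myh1 at 26.8 ± 14.7, 594 ± 889 and 198 ± 166, and Myh2 at 28.3 ± 19.9, 45.5 ± 46.3 and 36.8 ± 3.09 (SD, n = 3 each). Myh7, the slow form, had 1 read in Old-p21-High replicate 2 and 0 in the other 8 samples, which allows shares of up to 5.5e-04 to 0.00156% there (3 counts). Intervals and floors cover counting error only, since PCR copies are not independent molecules.

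The comparison of Old-p21-Low with Young-p21-Low fibres asked what differs with age when p21 is low. Fatty acid uptake and oxidation genes were higher in the older fibres as a list with a preset correlation only (adjusted p = 0.169 with an estimated correlation), and 1 of 30 members passed. Over all genes 5 passed the test. Slc25a20, the carrier that brings acylcarnitines into mitochondria (chromosome 9, 108662098 to 108684641), was at 175 ± 9.56 against 63.2 ± 12.1 CPM (SD, n = 3 each; log2 fold change 1.47, SE 0.19). Prr32 (10.5 ± 2.27 against 1.24 ± 0.552 CPM; 3.07, SE 0.36), Tmem37 (80.3 ± 34.3 against 11.9 ± 4.49 CPM; 2.76, SE 0.37) and Ccdc141 (6.03 ± 0.539 against 0.488 ± 0.140 CPM; 3.63, SE 0.47) were also higher. Prkag3, a muscle regulatory subunit of the energy sensor AMP-activated protein kinase (chromosome 1, 74738922 to 74748955), was lower, at 106 ± 5.67 against 351 ± 51.3 CPM (-1.73, SE 0.23). Each of the 5 had an edgeR adjusted p of 0.0322. The next genes by p in each direction did not pass, with Ccdc80 at 5.64 (edgeR adjusted p = 0.0715) and Ncoa7 at -5.66, Kcnq1ot1 at -2.07, Stard13 at -4.58 and Kcnu1 at -5.20 (edgeR adjusted p = 0.119 each). Kcnq1ot1 overlaps another annotated gene, Kcnq1.

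Of 11303 genes 5 differed, with 1185 at an unadjusted p below 0.05, and ranges did not overlap in 16.5% of genes, against 10% by chance. The count was 0 without any 1 Young-p21-Low sample, Old-p21-Low replicate 1 or 3 or the combined sample, 2 (Prr32 and Tmem37) without Old-p21-Low replicate 2, and Slc25a20 lost its call also without Old-p21-High replicate 3, while its log2 fold change stayed between 1.32 and 1.56 (highest adjusted p = 0.271). The count was also 0 with edgeR's legacy estimates, with only the 2 groups in the fit or with the replicate number as a block. It was 0 too with the number of detected genes as a covariate, 3 with a stricter filter on low counts, 4 with limma-voom and 208 with DESeq2. In simulated data for this comparison, over 11303 genes, 48.4% of genes changed 4-fold and 4.2% of those changed 2-fold were recovered.

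By camera with the preset correlation, 11 of 31 lists were called between Old-p21-Low and Young-p21-Low fibres, 5 higher and 6 lower, and 0 with an estimated correlation. Of 30 fatty acid genes 1, Slc25a20, rose (16 adjusted over the list alone, median 0.69, camera adjusted p = 4.9e-18), and of 23 tricarboxylic acid cycle genes 0 rose (10 adjusted over the list alone, median 0.48, camera adjusted p = 1.1e-07). Mitochondrial import (median 0.19, camera adjusted p = 0.00657), glycolysis (median 0.11, camera adjusted p = 0.0230) and oxidative phosphorylation genes (median 0.10, camera adjusted p = 0.0481) were called higher with 0, 4 and 0 members higher adjusted over the list alone. The lists called lower were fast-fibre sarcomere genes (median -0.48, camera adjusted p = 0.00275), immediate-early genes (-0.33, 0.00352), ribosomal proteins (-0.32, 0.00458), fibroblast markers (-2.36, 0.00458), cyclin-dependent kinase inhibitors other than Cdkn1a (-1.06, 0.0169) and circadian clock genes (camera adjusted p = 0.0481). Adjusted over the list alone, 1, 0, 0, 1, 1 and 0 of their members were lower and 1 sarcomere gene higher. With an estimated correlation, adjusted p = 0.169 for fatty acid and mitochondrial import genes, adjusted p = 0.280 for kinase inhibitors, adjusted p = 0.459 for immediate-early genes, adjusted p = 0.459 for fibroblast markers, and 0.655 to 0.911 for the other 6.

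The fatty acid, tricarboxylic acid cycle and mitochondrial import lists kept these camera calls without any 1 of the 9 samples, and the other 8 lists did not. Without Old-p21-Low replicate 1 the tricarboxylic acid cycle median was 0.30 and the immediate-early median -0.86. Without Young-p21-Low replicate 2 the mitochondrial import median was 0.31 and the oxidative phosphorylation median 0.29. Without Old-p21-Low replicate 2 the medians were 0.27 for oxidative phosphorylation, 0.18 for glycolysis, -0.55 for ribosomal proteins, -0.60 for immediate-early, -0.31 for fast sarcomere and -0.11 for circadian clock genes. The oxidative phosphorylation list lost its call without Young-p21-Low replicate 1 (median -0.02) or 3 (0.06), Old-p21-Low replicate 1 or 3 (0.03), Old-p21-High replicate 3 or the combined sample (highest adjusted p = 0.761). Its call was also lost with upper-quartile scaling (camera adjusted p = 0.0632), the replicate number as a block or a stricter filter on low counts. Offsets for GC content and length gave medians of 0.29 for oxidative phosphorylation and -0.19 for ribosomal proteins. Glycolysis lost it without Young-p21-Low replicate 1 or 2 or Old-p21-Low replicate 3 (median 0.02; highest adjusted p = 0.111), and ribosomal proteins without Young-p21-Low replicate 2 (median -0.06) or Old-p21-Low replicate 1 (median -0.12; highest adjusted p = 0.641). Circadian clock genes lost it without any 1 Young-p21-Low sample (median -0.12 without replicate 2), Old-p21-Low replicate 2 or 3 or the combined sample (highest adjusted p = 0.256). The circadian call was also lost with RLE or upper-quartile scaling, without the 20 genes of highest count and with the stricter filter (highest adjusted p = 0.0976). It held in 9 of 20 alternatives. The fast-fibre sarcomere list (adjusted p = 0.105) and kinase inhibitors (0.0883) lost theirs without Old-p21-Low replicate 2, immediate-early genes (0.0893) and kinase inhibitors (0.0683) without Old-p21-Low replicate 3, and fibroblast markers (0.0603) without Young-p21-Low replicate 2. The fast-fibre call was also lost without the 20 genes of highest count (median -0.43, adjusted p = 0.650). The fibroblast call was also lost with no filter on low counts (median 0, adjusted p = 0.0831). The fibroblast median of -2.36 moved to -1.19 without Young-p21-Low replicate 2 and to -4.60 without Old-p21-Low replicate 2. The number of called lists was 8 and 7 without Young-p21-Low replicates 1 and 2, 6 without Old-p21-Low replicate 3 and 7 with a stricter filter on low counts. No member of the other 20 lists passed over all genes (camera adjusted p from 0.0834 to 0.993), and adjusted over the list alone 2 heat shock genes and 1 calcium handling gene were lower, 1 atrophy and 1 slow sarcomere gene higher, and NRF2 targets 1 each way. Among the uncalled lists, the signs of median, mean and camera direction differed for proteasome subunits (median -0.02, mean 0.00, camera down), atrophy genes (median -0.03, mean -0.10, camera up), proliferation genes (median 0.08, mean -0.04, camera down) and the unfolded protein response.

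The comparison of Old-p21-High with Young-p21-Low fibres joined the differences of age and p21 level. Energy metabolism genes were lower and proteasome and NF-kB genes higher in Old-p21-High fibres. Of 59 oxidative phosphorylation subunits 56 fell (59 adjusted over the list alone, median -1.28), of 23 tricarboxylic acid cycle genes 16 fell (18 adjusted over the list alone, median -0.95), and of 30 fatty acid genes 8 fell (10 adjusted over the list alone, median -0.30). Of 29 glycolysis and glycogen genes 18 fell and 1, the glycogen branching enzyme Gbe1, rose (19 and 2 adjusted over the list alone, median -1.34). Sdhd was at 227 ± 13.6 against 723 ± 57.7 CPM, Idh3a at 488 ± 56.2 against 1784 ± 169.97 CPM, Acadm at 83.1 ± 14.4 against 312 ± 38.1 CPM, Tpi1 at 263 ± 128 against 4065 ± 302 CPM and the muscle phosphoglycerate mutase Pgam2 at 753 ± 320.03 against 5126 ± 1269 CPM (SD, n = 3 each). Of 17 fast-fibre sarcomere genes 7 fell (9 adjusted over the list alone, median -1.34), including Mylpf, the fast regulatory light chain, at 3595 ± 1465 against 14420 ± 3369 CPM and Ampd1, a muscle AMP deaminase, at 691 ± 235 against 2780 ± 531 CPM. Of 26 calcium handling genes 7 fell and 2 rose (9 and 3 adjusted over the list alone, median -0.45), with Sypl2 at -1.95 (SE 0.31) and the kinase Camk2a at -1.07 (SE 0.24) on the log2 scale. Of 32 proteasome subunits 17 rose (22 adjusted over the list alone, median 0.91), including Psma5 at 94.0 ± 15.8 against 36.2 ± 1.81 CPM. Of 17 NF-kB genes 10 rose and 0 fell (11 and 1 adjusted over the list alone, median 1.54), the rises including Birc3 (4.03, SE 0.34), Ripk2 (2.77, SE 0.38) and Nfkb2 (4.00, SE 0.78). Tpi1, Camk2a and Nfkb2 overlap another annotated gene.

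For these 8 lists the camera adjusted p values with the preset correlation were 2.2e-36 (oxidative phosphorylation), 2.4e-10 (tricarboxylic acid cycle), 0.00130 (fatty acid), 2.4e-10 (glycolysis), 9.1e-08 (fast sarcomere), 0.0161 (calcium handling), 4.0e-09 (proteasome) and 1.2e-05 (NF-kB). None held with the correlation taken from the data: adjusted p = 0.421 with an estimated correlation for the proteasome and adjusted p = 0.394 with an estimated correlation for the other 7. The calcium handling list also lost its call without Old-p21-High replicate 2 (camera adjusted p = 0.0794). Over the alternatives the fast sarcomere median ranged from -2.06 to -0.997. Its lowest value came without the 20 genes of highest count, where list members among those 20 were left out. Markers of other cell types took 0.119% of reads in Old-p21-High and 0.114% in Young-p21-Low samples on average. Over all members of the oxidative phosphorylation, tricarboxylic acid cycle, fatty acid and glycolysis lists the median was -1.17. It was -0.68 with the number of detected genes as a covariate.

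Over all genes 2151 of 11303 differed between Old-p21-High and Young-p21-Low fibres, 1010 higher and 1141 lower, and 1678 changed at least 2-fold. At an unadjusted p below 0.05 there were 3835 genes, and ranges did not overlap in 39.0% of genes, against 10% by chance. Igfn1 (chromosome 1, 135953578 to 136006342) had 0 reads in the Young-p21-Low samples and was at least 653-fold higher in Old-p21-High fibres, against a floor of 3 counts over the group. Krt18 (chromosome 15, 102028216 to 102032026) also had 0 reads there, but ranged from 2.11 to 876 CPM in the Old-p21-High samples. Its log2 fold change, a fitted value that cannot be measured against 0 reads, fell from 15.61 to 10.61 without Old-p21-High replicate 2. Its call was lost with limma-voom (adjusted p = 0.296) and with only the 2 groups in the fit. Rassf4, the pro-apoptotic BCL2 family member Bid, Emb and Ggt6 had 1 or 2 reads there, with ratios of 1325 (95% counting interval 237 to 52346), 755 (209 to 6242), 495 (137 to 4093) and 421 (116 to 3482). These intervals cover counting error only: without single samples the log2 fold change of Rassf4 was at 8.59 to 11.78, of Bid at 7.14 to 11.92 and of Ggt6 at 7.53 to 11.16. Ces2c changed by 7.72 (SE 1.14) and Lgals3, a galectin, by 7.39 (SE 2.30). The largest falls were Gpr3 (-7.68, SE 1.91), Smco1 (-6.15, SE 0.27), Nrep (-6.01, SE 0.55), Emid1 (-5.79, SE 0.61), Perm1 (-5.63, SE 0.48), Tppp3 (-5.58, SE 0.85), Kbtbd13 (-5.55, SE 0.74) and Mettl21c (-5.50, SE 1.34).

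Of these 16 genes, 4 lost their edgeR call without some single sample. Emb lost it without any 1 Young-p21-Low or Old-p21-Low sample or Old-p21-High replicate 2, where it was at 4.26 (highest adjusted p = 0.230). Lgals3 lost it without any 1 Young-p21-Low sample or Old-p21-High replicate 2, where it was at 4.29, or 3 (highest adjusted p = 0.164). Gpr3 lost it without Young-p21-Low replicate 2 or any 1 Old-p21-High sample (-10.06 to -5.85, highest adjusted p = 0.0764), and Mettl21c without Young-p21-Low replicate 2, where it was at -2.82, Old-p21-High replicate 2 or the combined sample (highest adjusted p = 0.0759). Without the combined sample Tppp3 was at -8.47, Kbtbd13 at -7.26 and Nrep at -6.79. Emid1 was at -5.07 without Old-p21-High replicate 2 and Ces2c at 8.98 without Young-p21-Low replicate 1. The number of changed genes was 1363, 1157 and 1094 without Young-p21-Low replicates 1, 2 and 3, and 19 with the number of detected genes, 11942 to 12361 in Young-p21-Low and 12669 to 13746 in Old-p21-High samples, as a covariate. With edgeR's legacy estimates, whose share of false calls in the simulated counts was lower, it was 1717.

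Calls were then compared between comparisons that share samples. Prr32, Tmem37 and Ccdc141 were higher both in Old-p21-High and in Old-p21-Low than in Young-p21-Low fibres, 3 genes where independent lists would share 0.357. In 50 simulations of unchanged groups with shared samples, where few genes are called at all, 0 were shared. The correlation of the fold changes of these comparisons was 0.40, below the mean of 0.50 in the simulations, and the covariance was 0.52 against 0.26. Old-p21-High fibres shared 570 higher and 744 lower genes between the comparisons with Old-p21-Low and with Young-p21-Low, and 1 gene, Ccdc141, was called in opposite directions. Independent lists would share 78.2 and 111 genes, and the simulations gave a mean of 0.04 and a highest value of 1 over both directions. Here the correlation was 0.74 against 0.49 in the simulations, and the covariance 1.33 against 0.25. With 3 samples the shared group could not be split into parts of at least 2, so part of the excess may come from the shared samples.

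Markers of other cell types were few in all groups. Lists of satellite, endothelial, fibroblast, immune, smooth muscle, Schwann, tendon, adipocyte and red blood cell genes together took 0.108 to 0.130% of reads in Old-p21-High, 0.0700 to 0.0911% in Old-p21-Low and 0.110 to 0.116% in Young-p21-Low samples. Between Old-p21-High and Old-p21-Low fibres 1 of 9 satellite cell genes fell, Itm2a, at means of 120.4 against 511 CPM, with 883 CPM in Young-p21-Low fibres. Of 4 fibroblast markers 1, Smoc2, rose, and its mean was 126 CPM in Young-p21-Low fibres. Schwann cell markers rose in 1 of 3 cases, tendon markers rose in 1 and fell in 1 of 2, and none of 1 endothelial, 4 immune, 3 smooth muscle and 1 adipocyte genes tested passed. Adjusted over the list alone these counts were the same, except that 1 endothelial and 1 immune gene rose. Between Old-p21-High and Young-p21-Low fibres 1 Schwann, 1 tendon and 1 endothelial marker rose and 1 satellite, 1 tendon and 1 smooth muscle marker fell (2, 1, 1, 1, 1 and 1 adjusted over the list alone), while between Old-p21-Low and Young-p21-Low none passed over all genes. No red blood cell gene passed the filter for testing, and no mitochondrially encoded gene was in the table.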

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

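The fits with 10 columns, with column 1 or column 4 alone, and with offsets for GC content and length were chosen only after the data were seen. The count of changed genes stayed within 1.5 times in 22 of 25 alternatives between Old-p21-High and Old-p21-Low, 12 of 25 between Old-p21-Low and Young-p21-Low, and 21 of 25 between Old-p21-High and Young-p21-Low, and no named gene or called list changed direction past its threshold. With the number of detected genes as a covariate the counts were 91, 0 and 19 in the same order. Of the called genes taken by the rule, Cdkn1a aside, 57 of 78 and 70 of 76 lost their calls against Old-p21-Low and Young-p21-Low in the comparisons of Old-p21-High. The number of detected genes holds 69.8% of its variance between groups. The median standard error rose from 0.37 to 0.60 and from 0.37 to 0.64 in the comparisons of Old-p21-High, where 100% and 99.9% of the called genes kept their direction. Between Old-p21-Low and Young-p21-Low the stricter filter gave 3 genes (fewer genes were tested), DESeq2 208 (5 shared with edgeR), and edgeR's legacy estimates, only the 2 groups compared and the replicate block 0 each; the cause was not tested. Leaving out each sample gave 1005 to 1943, 0 to 7 and 1094 to 2091 genes, and -0.55 to 0.14 for Cdkn1a between Old-p21-Low and Young-p21-Low (adjusted p 0.539 to 0.975 over all alternatives). Lists called between Old-p21-Low and Young-p21-Low numbered 6 to 11 without single samples and 7 with the stricter filter, and 0, 0 and 0 lists were called with an estimated correlation. Genes called in the same direction in both comparisons with Young-p21-Low numbered 84 with DESeq2 and 1 with the stricter filter. Myh4 CPM in place of its share differed by -3036 CPM between Old-p21-High and Young-p21-Low. Whether replicate numbers pair the samples was not settled: same-numbered samples correlated by -0.07 to 0.13, with 4 of 9 pairs over 0.1. Other pairs correlated by -0.18 to 0.14, and 5 of 9 samples correlated best with their own number in both other groups. The replicate block gave 2089 and 2256 genes in the comparisons of Old-p21-High, and 10 in place of 11 lists between Old-p21-Low and Young-p21-Low, without oxidative phosphorylation. Counts near 0 limit Cdkn2a, Myh7 and the folds of genes with 0 to 2 reads in a group.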

Other observations

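The tests of a glycolytic shift, of other cell types, of the shared columns, of a fibre type difference and of genes that vary together were chosen only after the results were seen, and the offsets for GC content and length after the data were seen.

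Further gene groups differed between Old-p21-High and Young-p21-Low fibres in members but not as called lists (camera adjusted p from 0.1002 to 0.972 with the preset correlation). Of 29 p53 targets 6 rose and 3 fell (6 and 3 adjusted over the list alone), with Eda2r at 1602 ± 309 against 89.1 ± 83.6 CPM, Mdm2 at 364 ± 17.5 against 122 ± 14.2 CPM and Tigar, a regulator of glycolysis, at -1.70 (SE 0.30). Of 23 atrophy genes 4 rose and 2 fell (5 and 3 adjusted over the list alone), with the ubiquitin ligases Trim63 at 3221 ± 466 against 443 ± 237 CPM, Fbxo32 at 1725 ± 339 against 465 ± 175 CPM and Fbxo30 at 492 ± 55.6 against 89.2 ± 22.1 CPM. Of 26 denervation and neuromuscular junction genes 5 rose and 6 fell (8 and 8 adjusted over the list alone), with Musk at 3.82 (SE 0.32), Hdac4 at 2.35 (SE 0.24) and Ache at -2.64 (SE 0.27). Of 21 secreted factors 3 rose and 2 fell (3 and 2 adjusted over the list alone), with Cxcl10 at 4.05, Serpine2 at -2.66 and Il15 at -4.23 on the log2 scale. Of 28 NRF2 targets and antioxidants 4 rose and 3 fell (5 and 3 adjusted over the list alone), with Nqo1 at 1.63, Gsr at 1.06 and the catalase gene Cat at 2.35. Of 37 autophagy and lysosome genes 5 rose and 2 fell (5 and 2 adjusted over the list alone), with Atp6v1a at 2.34, Atp6v1h at 1.64 and Wipi1 at 0.99. Each of these edgeR calls held without any 1 of the 9 samples, though without Young-p21-Low replicate 2 Eda2r was at 5.29 in place of 4.17 and Cxcl10 at 5.18, and Serpine2 at -3.38 without the combined sample. The signs of median, mean and camera direction differed for secreted factors (median -0.03, mean 0.31, camera down), stretch genes (median -0.43, mean -0.06, camera up), ribosomal proteins and proliferation genes (camera down for both), and for denervation and circadian clock genes.

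The metabolic pattern between Old-p21-High and Old-p21-Low fibres was the fall of oxidative phosphorylation, tricarboxylic acid cycle, fatty acid and glycolysis genes, with a median of -1.38 over 139 members. Offsets for GC content and transcript length moved other genes by a median of 0.126 and left the members at -1.29 (quartiles -1.73 to -0.94), with 111 in place of 118 called, which argues against these as the whole cause. A shift to a more glycolytic fibre type would raise glycolysis genes, whose median was -1.44 with an upper quartile of -0.91, which argues against it as the whole cause. It remains open as a part, since the Myh4 share was at least 99.49% in Old-p21-High and at most 99.15% in Old-p21-Low fibres. Of 10 slow-fibre and oxidative-fibre genes 2 fell and 1 rose. Dilution by RNA of other cells would lower the fibre's own genes at least as much as genes that other cells express too. Of 17 fast sarcomere genes 7, Myh4 among them, lay above -1.38 by more than 2 standard errors, where chance would give 0.425 for independent genes. These genes vary together (estimated correlation 0.565) and -1.38 is the median of lists picked for their fall, so 0.425 is no firm reference. Of 26 calcium handling genes 21 lay above -1.38 likewise. Some genes of both lists are expressed in other cells too. These values argue against dilution as the whole cause. A smaller part remains open, since the share of reads in markers of other cells was higher in Old-p21-High fibres (0.119 against 0.0786%). The fast sarcomere median went from -0.85 to -1.54 without the 20 genes of highest count, but list members among those 20 were left out. The median over all genes hardly moved (0.0759 against 0.0819). That shift thus mainly reflects which members stayed in the list and does not decide on dilution. The marker lists did not move alike. The fibroblast share was higher (0.0556 against 0.00147%), with Smoc2 at 439 against 11.6 CPM, and the satellite cell share lower (0.0362 against 0.0643%). The test of dilution was the third one tried: by the marker share alone it was excluded, and by the fast sarcomere quartiles, -1.45 to -0.21, which include -1.38, it was left undecided. The p21 level remains an untested biological explanation, as does any difference between the mice or in the preparation that follows the groups.

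The pattern in the columns of Old-p21-High replicates 1 and 4 was their near identity in the median gene, with 124 gene entries far lower in replicate 4 and 13 far lower in replicate 1. A median chi-square of 0.838, against at least 7.77 in other pairs, argues against separate fibres, and 0.129 in genes with 20 to 100 reads, below the 0.455 of independent draws, argues against separate sequencing runs of 1 library. The ratio stepped by a median of -0.18 on the log2 scale near 90.7 Mb on 16 of 16 chromosomes tested, and against the other samples the step was -0.16 in replicate 1 and 0.03 in replicate 4. This is consistent with the same reads having been aligned or counted differently, as a hypothesis. No biological explanation was tested.

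The pattern between Old-p21-Low and Young-p21-Low fibres was a higher median of the fatty acid list, 0.69. It stayed at 0.53 to 0.89 without any 1 of the 6 samples, which argues against a single sample as the cause. A more oxidative fibre type remains open, because the lists pointed both ways. Oxidative phosphorylation genes had a median of 0.10 (upper quartile 0.34), and the fatty acid median was still 0.53 without Old-p21-Low replicate 1, the sample with the most Myh1. The median was 0.48 for tricarboxylic acid cycle genes, 0.34 for slow sarcomere genes and -0.48 for fast sarcomere genes, as such a fibre type would have it. No member of these lists passed the edgeR test over all genes. With an estimated correlation, camera adjusted p = 0.655 for the tricarboxylic acid cycle list and 0.706 for each sarcomere list. The fast sarcomere call was also lost without the 20 genes of highest count (camera adjusted p = 0.650). Members of the fatty acid list that vary together between fibres also remain open (adjusted p = 0.169 with an estimated correlation). The highest size of the fatty acid median in the other 9 splits was 0.50. Age remains an untested biological explanation.

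Of the 10 splits of the 6 samples in each comparison, 1, the real one, gave as many called genes, with 1979, 5 and 2151 genes between Old-p21-High and Old-p21-Low, Old-p21-Low and Young-p21-Low, and Old-p21-High and Young-p21-Low. The highest of the other splits was 0 in each (edgeR, at an unadjusted p below 0.05 up to 858, 826 and 900 genes), and 10 splits are too few for a share under 0.05.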
